A study of Mus musculus with 44 samples.

How the data were processed

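Gene expression was measured by the authors in 44 samples of mouse cells, each hybridised to its own array of a 1-colour Agilent mouse whole-genome design. Per the labels, total RNA was isolated with a miRNeasy kit and labelled with Cy3 by linear amplification. Per the file headers, each scanner file was made with Agilent Feature Extraction 10.7.3.1 and gives the processed signal of each spot as an intensity, background-subtracted and detrended within the array and not normalised between arrays. Each scanner file also gives the raw mean intensity and the local background intensity of each spot and its quality calls. The deposited value table holds log2 values for 44 columns. Its method is not stated by the authors. The sorted values of its columns differed by at most 0.00162, as they would after quantile normalisation, with a column median of 7.21 and a lowest value of 5.66, and whether it was centred or scaled otherwise is unknown. By rank correlation, 34 of its columns matched the scanner file of their own sample best and 10 matched the scanner file of another sample, 6 of them among the pluripotent lines and 4 with the replicates of a group crossed. The lowest best Spearman rho of a column with a scanner file was 0.9938, the highest second best was 0.9825, and the lowest rho with a column's own file was 0.8062. The columns of ES R1, ES Bruce, aiPS 8 and aiPS 22 were among those that matched another sample. By the table's labels the replicates of ES Bruce would be the scanner files of aiPS 8 and ES R1, in which the Y-linked gene Ddx3y stood at a log2 level of -7.01 and 0.45, which replicates of a line would not show. The scanner files were therefore used for the reported values and the value table only as an alternative, both as labelled and with each column given to the scanner file it matched.

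Control spots were left out, which left 59305 spots for 55681 probes, and spots that the scanner software marked as non-uniform or as outliers were dropped before averaging the spots of a probe. The 227 probes left without a usable spot on an array were not tested. Processed intensities were put on the log2 scale and each array was scaled to its own 75th percentile, so a level of 0 is the 75th percentile of the array. A probe was kept when it was well above background on every array of at least 1 group, which kept 51247 probes. Probes were named from the array annotation, 26300 of them through their accession, and 2839 names were updated from the gene table supplied with the data. A total of 26816 probes carried a gene symbol, and probe positions are in mm9 (NCBI37). The brightest probe stood for each gene name, which gave 34172 features, 18721 of them with a gene symbol. No reference genome came with the series, so probe sequences were not mapped again.

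Differences were tested with limma 3.58.1 in R 4.3.3, with the R package data.table (1.17.8). A fit over all arrays with 1 mean per group was used for each comparison of groups. The pulse difference over the time course was fitted on the mean of both arrays of each group with the time point as a block, over 8 pairs, leaving out 24 h because the pulsed 24 h arrays lay on a slide that shared no group with the others. The induced pluripotent stem cell (iPS) lines were compared with the embryonic stem cell (ES) lines on 1 mean per line. P-values were adjusted by the Benjamini-Hochberg method over all features tested, and a feature was called at an adjusted p under 0.05 and a fold of at least 2. The p-values measure only the spread between arrays that the labels call technical replicates, except in the paired fit and the fit on lines. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. Similarity to ES lines was compared between arms by an exact two-sided sign-flip permutation test over 8 time points, whose smallest possible p is 0.00781. Correlations across time points were tested by exact permutation, and the correlation across groups with 1e+05 permutations. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the figures.

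The 21 gene lists, the comparisons, the tests and the rule for naming genes were chosen before the data were examined. The rule names a fixed panel of 26 genes of B cells, myeloid cells, pluripotency, epithelium, mesenchyme and chromatin, whatever their values. For each comparison with list tests it also names the 10 largest rises and the 10 largest falls among called features whose arrays did not overlap and that were well above background on every array of the brighter side, without unnamed features and antigen receptor segments. For each list it adds up to 4 members with the largest called change and up to 2 with the smallest change. Where a gene was not above background on any array of a side, its change is given as at least N-fold, computed with each array of that side set to the lowest signal that the scanner software called well above background on that array or to the gene's own signal, whichever was higher. No fold is given where both sides were below background, other than among the changes of sign under other processing.

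The alternatives were quantile normalisation of the processed signal; normexp background correction of the raw mean signal (offset 50) with quantile normalisation; the authors' value table; no filter on dim probes; the mean over the probes of a gene; replicate number as a block; slide as a fixed or as a random block (correlation 0.188); each array left out in turn; and group means fitted with a natural spline of time (3 degrees of freedom) in each arm. For the time course they also included 24 h, left out 0 h and left out each time point. Chosen after seeing the data were 4 further alternatives: only the 25315 features with a log2 level of -2 or more on every array of a group, the value table matched to scanner files, the paired fit up to 48 h, and quantile normalisation without the first unpulsed 0 h array. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the other groups.

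The tests were checked on simulated data with the gene means and spreads of the arrays. The noise was independent between genes, with no shift of a whole array, so the false calls below do not cover such shifts. In these data 67, 67 and 66 of the 34172 features were changed by a log2 of 1, 2 and 3. The comparison of the arms at 0 h recovered 17.9%, 59.7% and 78.8% of them, with 8 false calls. The paired fit recovered 1.49%, 20.9% and 78.8%, with 5 false calls. The fit on lines recovered 0% at each size with limma, with 0 false calls, so that it could not call a gene of these sizes.

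Arrays have no sequencing depth, and the number of arrays limits the precision. The array positions came from 6 slides. Slides 1 to 5 were scanned on 1 day and slide 6, with 8 arrays of 4 groups, on another. The groups on slide 6 were pulsed 24 h, ES Bruce, iPS 26 and aiPS 22, and none of them was on another slide, so for these the slide cannot be told apart from the group.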

Results

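Messenger RNA levels were measured in 44 samples of mouse cells, with 1 array per sample. Per the labels, B cell precursors carrying the surface protein CD19 were taken from bone marrow. They were reprogrammed on OP9 stromal feeder cells by Oct4, Sox2, Klf4 and Myc (OSKM), switched on with doxycycline. These factors turn somatic cells into induced pluripotent stem cells. In the pulsed arm the cells had first received an 18 h pulse of C/EBPα, a transcription factor of myeloid cells, induced with estradiol. The unpulsed arm had no such pulse. Each arm was sampled at 0, 3, 6, 12, 24, 48, 96, 144 and 192 h, with 2 arrays per arm and time point that the titles call technical replicates. The last time point is 192 h in the titles and 196 h in a second field. The series also held embryonic stem cell (ES) lines R1 (1 array) and Bruce (2 arrays) and induced pluripotent stem cell (iPS) lines iPS 26 (2 arrays), aiPS 8 (1 array) and aiPS 22 (2 arrays). The labels state that cells were sorted by flow cytometry to remove feeder and dead cells.

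Between 51.0% and 87.5% of spots were well above background on an array, and no spot was saturated. Replicate arrays correlated at a Pearson r of 0.938 to 0.994 across genes (median 0.988, 21 pairs), and arrays of different groups at 0.711 to 0.992 (median 0.907, 925 pairs). Genes are not independent replicates in these correlations. The lowest of the replicate values belonged to the unpulsed 0 h pair, in which 81.7% and 67.1% of spots were well above background. The negative control spots of its first array had a mean signal of 90.3, against 33.9 to 71.5 on the other arrays. Pulsed 24 h, ES Bruce, iPS 26 and aiPS 22 shared a slide with no other group, so for them slide and group cannot be told apart. Changes are log2 differences of group means ± standard error from limma, with n = 2 arrays per group unless stated. Levels are given ± SD, and p-values are adjusted over all 34172 features. List counts adjusted over the list alone equal those adjusted over all genes except where both are given. Many comparisons shifted all genes together, so list medians are also given relative to the median of all features (as relative values). A second median, at the bound, is given where it differed by over 0.3. In it, a member below background on every array of a side was set to the bound of its fold, or to 0 where it was below background on both sides.

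What the pulse had changed before OSKM was asked by comparing pulsed with unpulsed cells at 0 h. Cebpa (2.97 ± 0.16, adjusted p = 4.89e-13), measured on chromosome 7 at 35906517 to 35906576 (mm9), was higher in pulsed cells. Without the pulse Cebpa also rose, from -1.25 at 0 h to 1.31 at 48 h, when the stromal list below stood at 2.35. Whether Cebpa responded to the pulse or came with stromal cells was not tested. B cell identity genes fell together, 28 of 29, with a median log2 change of -3.17, or -2.35 relative to all features, whose median was -0.82. Among them were the Fc receptor-like gene Fcrla (-4.98 ± 0.45), the recombinase Rag1 (-4.72 ± 0.34), the kinase Blk (-4.42 ± 0.36) and the master regulators Pax5 (-3.66 ± 0.38) and Ebf1 (-1.66 ± 0.23). Cd19 (-2.91 ± 0.38, adjusted p = 9.67e-07), probed on chromosome 7 at 133552524 to 133552583, also fell. Genes of stromal feeder cells rose in 21 of 24 cases and none fell, with a median of 2.82 and 3.64 relative to all features. They included the smooth muscle genes Tagln (4.39 ± 0.23) and Acta2 (3.91 ± 0.21), the growth factor receptor Pdgfrb (3.86 ± 0.20) and the collagen cross-linking enzyme Lox (3.75 ± 0.13). Col1a1 (2.84 ± 0.16), a chain of type I collagen, also rose.

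Among the largest falls were the proteases Prss34 (-6.69 ± 0.71), Mcpt8 (-5.83 ± 0.68) and Cpa3 (-5.61 ± 0.45), the IgE receptor chain Fcer1a (at least 30.3-fold) and the granule proteins Ltf (-5.30 ± 0.28) and S100a8 (-5.06 ± 0.33). The myeloid list as a whole went both ways, with 7 genes higher and 10 lower of 32 (median -0.24), and did not pass its test. The macrophage genes Csf1r (-0.37, adjusted p = 0.184), Lyz2 (-0.12, adjusted p = 0.628) and Itgam (0.84, adjusted p = 0.219) were not called. For Itgam 2 dimmer probes stood lower in pulsed cells, at -4.59 against -3.26 and at -4.02 against -1.68, and the chosen probe was as bright in ES R1 (3.38) as in unpulsed 0 h cells (2.92). Among the largest rises were those of the matrix protein Mgp (5.38 ± 0.12, adjusted p = 9.42e-19), the lipoprotein Apoc1 (5.13 ± 0.41), the sodium pump subunit Atp1a3 (5.05 ± 0.20) (-0.27 for another probe), the fatty acid receptor Gpr84 (4.98 ± 0.39) and the matrix signal Ccn2 (4.25 ± 0.22).

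Mesenchymal regulators rose in 10 of 18 cases and fell in 3 (median 1.25, relative 2.07). The repressors Snai1 (3.40 ± 0.13) and Snai2 (2.53 ± 0.11) and the transcription factor Foxc2 (3.52 ± 0.29) were among them. Genes of the list of p53 targets and senescence, called p53 targets below for short, rose in 12 of 22 and none fell (median 1.20, relative 2.02). They were led by the death receptor Tnfrsf10b (2.69 ± 0.26), Zmat3 (2.59 ± 0.30) and the cell cycle inhibitor Cdkn2b (2.52 ± 0.25). The medians of both lists followed a course like that of the stromal list. Against unpulsed 0 h they stood in pulsed cells at 1.25 and 1.20 at 0 h and -1.41 and -0.68 at 24 h, when the stromal list stood at 2.82 and -1.93. In unpulsed cells at 48 h they stood at 0.94 and 1.57 and the stromal list at 2.35. Whether these lists responded to the pulse or came with stromal cells was not tested. Cell cycle genes fell in 22 of 30, or 23 adjusted over the list alone (median -1.37, relative -0.54), with the topoisomerase Top2a (-1.82 ± 0.12) and the licensing factor Cdc6 (-1.93 ± 0.40) among them. Interferon response genes fell in 17 of 28 (median -1.29, relative -0.47), with Oasl1 (-4.54 ± 0.19) and Mx1 (-4.04 ± 0.14) among them. These lists, the B cell list and the stromal list passed the list test also with an estimated correlation.

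Other lists passed at the preset correlation and lost the call with an estimated one. Genes of T and NK cells were lower in 15 of 18 cases (median -2.17, relative -1.34), with the receptor chain Cd3d (-3.54 ± 0.27). The list had adjusted p = 0.169 with an estimated correlation. Epithelial genes were lower in 15 of 23 (median -2.07, relative -1.25, at the bound -1.66), with the adhesion protein Cdh1 (-3.40 ± 0.36). They had adjusted p = 0.607 with an estimated correlation. Genes of trophoblast and primitive endoderm were higher in 6 and lower in 3 of 19, with the basement membrane genes Col4a1 (3.69 ± 0.10) and Lamb1 (3.43 ± 0.17). Their median was -0.05 and their mean 0.31, the test ran upward, and adjusted p = 0.212 with an estimated correlation. Immediate early and heat shock genes were higher in 6 and lower in 3 of 19 (median 0.24, relative 1.06), with the haem oxygenase Hmox1 (2.81 ± 0.15) (adjusted p = 0.0721 with an estimated correlation). Chromatin regulators were lower in 11 of 31, with Ezh2 (-2.25 ± 0.23) and Uhrf1 (-1.84 ± 0.14). Their test ran downward while their median (-0.69) gave a relative value of 0.13, and they had adjusted p = 0.204 with an estimated correlation. MYC targets of ribosome biogenesis were lower in 2 of 24, with the nucleolar protein Ncl (-1.05 ± 0.12). Their test also ran downward, at a relative median of 0.18, and had adjusted p = 0.393 with an estimated correlation.

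The remaining lists did not pass. Of the 4 reprogramming factors 1 was higher and 2 lower (median -0.74, at the bound -0.23), of which Sox2 was below background in both groups. Klf4 (1.59 ± 0.44) was higher, and lost its call under quantile scaling (adjusted p = 0.0629), while Pou5f1 (-2.25 ± 0.49), which encodes Oct4, was lower. The unpulsed 0 h pair stood at -3.01 ± 1.97 (SD) for Pou5f1, and without the first of its arrays 0 of the 4 factors were called. Pluripotency genes were higher in 1 and lower in 14 of 34 (median -1.51, at the bound -1.11). Inflammatory genes were higher in 6 and lower in 5 of 21 (6 and 6 adjusted over the list alone), with Il1b (2.55 ± 0.44) higher and Tnf (-2.77 ± 0.18) lower. Glycolysis genes were lower in 3 of 17 and germline genes in 8 of 18, or 10 adjusted over the list alone (germline median -1.77, at the bound -0.70). Of 10 genes of the 2-cell stage, 1 was higher and 1 lower (median -0.31, at the bound 0). Of 17 erythroid and megakaryocyte genes 1 was higher and 9 lower (10 adjusted over the list alone). Of 14 housekeeping genes 1 was lower, the transferrin receptor Tfrc (-2.67 ± 0.15). Of the called members of lists, 3 germline genes, 1 gene of the 2-cell stage and 1 trophoblast gene were also below background in both groups. Median and mean differed in sign for the inflammatory list (0.33 and -0.16), and the test ran against the median in the myeloid, glycolysis and 2-cell-stage lists.

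In all, 13631 features were called at 0 h, 3016 higher and 10615 lower in pulsed cells, and with quantile scaling 9202, 4721 higher and 4481 lower. The count was 7104 without the first unpulsed 0 h array, 6629 without the second pulsed 0 h array, and 133 when the spread was taken around a curve of time. Under quantile scaling 2 epithelial genes were higher and 7 lower, and 5 pluripotency genes higher and 8 lower. In the same scaling 4 genes of the 2-cell stage and 10 trophoblast genes were higher and 0 lower, 2 germline genes were lower, and 3 erythroid genes were higher and 5 lower. Without the first unpulsed 0 h array 1 epithelial gene was higher and 5 lower, and 4 pluripotency genes higher and 5 lower. No germline gene was then called, 9 trophoblast genes were higher and 0 lower, and 2 erythroid genes higher and 4 lower. MYC targets were lower in 6 cases without that array and in 0 under quantile scaling, where the epithelial and immediate early lists lost their calls (adjusted p = 0.0943 and 0.111). The quantile medians of the glycolysis, 2-cell-stage and trophoblast lists were 0.03, 1.02 and 1.06, against negative ones above. No slide held both groups, and with slide as a block the median of the B cell list was -3.20.

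OSKM without the pulse was followed in unpulsed cells at each time point against 0 h. Cd19 (0.55, adjusted p = 0.267) was at 5.96 ± 0.07 (SD) at 192 h, against 5.41 ± 0.05 at 0 h. B cell identity genes were higher in 3 and lower in 1 of 29 (median 0.38, relative 0.79), with Rag1 (2.01 ± 0.34), the surface protein Ms4a1 (1.22 ± 0.26) and Cd24a (1.04 ± 0.16) higher. At 192 h Pou5f1 (-0.73, adjusted p = 0.253) was not called, and Sox2 was below background on both sides. Whether these probes detect induced OSKM was not tested. Pluripotency genes were lower in 11 of 34, or 12 adjusted over the list alone (median -1.03, relative -0.62, at the bound -0.40). They had adjusted p = 0.526 with an estimated correlation, and under quantile scaling 2 were higher and 3 lower.

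Myeloid genes fell in 23 of 32 cases and rose in 1 (median -3.76, relative -3.35, at the bound -3.33). The neutrophil granule genes Mpo (-11.48 ± 0.56), S100a9 (-11.14 ± 0.15), S100a8 (-10.73 ± 0.33), Ltf (at least 528-fold) and Ctsg (-9.02 ± 0.34) fell. So did the basophil protease Mcpt8 (at least 228-fold) and the cytotoxic protease Gzma (-8.30 ± 0.16). Interferon genes fell in 23 of 28 (median -1.74, relative -1.33), with the chemokine Cxcl10 (-4.21 ± 0.37) and the regulator Irf7 (-3.46 ± 0.14). Inflammatory genes fell in 8 and rose in 1 of 21 (median -0.46), with Ccl4 (-4.89 ± 0.27) and Ccl5 (-3.55 ± 0.21). Immediate early genes fell in 7 of 19 (median -0.83, relative -0.42), with Fosb (-4.69 ± 0.18), Atf3 (-3.77 ± 0.13) and Fos (-3.20 ± 0.40). Genes of the p53 and senescence list rose in 6 of 22 (median 0.64, relative 1.05). Among them was Cdkn2a (3.01 ± 0.12, adjusted p = 8.71e-15), a cell cycle inhibitor that restrains reprogramming, at 3.89 ± 0.05 (SD) against 0.89 ± 0.10 at 0 h. Stromal genes rose in 3 and fell in 1 of 24 (median 0.45, relative 0.86), with Col3a1 (2.25 ± 0.16) and the chemokine Cxcl12 (2.21 ± 0.27). These lists and the B cell list held with an estimated correlation, and the B cell list lost its call under quantile scaling (adjusted p = 0.0733).

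Further lists passed only at the preset correlation. T and NK genes were lower in 10 of 18 (median -2.06, at the bound -0.81), with the cytotoxic protease Gzmb (-6.18 ± 0.37), and had adjusted p = 0.132 with an estimated correlation. Erythroid genes were lower in 11 of 17, or 14 adjusted over the list alone (median -1.63), with the platelet factor Pf4 (-4.14 ± 0.19). Under quantile scaling 5 were lower, and the list had adjusted p = 0.0726 with an estimated correlation. Germline genes were lower in 7 of 18, or 10 adjusted over the list alone (median -1.71, at the bound -0.32; adjusted p = 0.475 with an estimated correlation). Housekeeping genes (median 0.28), cell cycle genes (0.16), glycolysis genes (0.13) and MYC targets (0.17) had 0 members called. Their medians lay above that of all features, -0.41, and they had adjusted p = 0.132, 0.154, 0.154 and 0.193 with an estimated correlation. Chromatin regulators (median 0.17) were lower in 2 of 31, or 1 adjusted over the list alone (adjusted p = 0.224 with an estimated correlation). Mesenchymal genes were higher in 1 and lower in 2 of 18, with a median of 0.33, a mean of -0.08 and an upward test (adjusted p = 0.193 with an estimated correlation).

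Epithelial genes did not pass. They were higher in 0 and lower in 9 of 23, or 10 adjusted over the list alone (median -1.17, at the bound -0.53), and 5 were higher and 3 lower under quantile scaling. Nor did the reprogramming factors (lower in 1 of 4), genes of the 2-cell stage (lower in 2 of 10, median -0.89, at the bound 0) or trophoblast genes. The last were higher in 1 and lower in 4 of 19, 5 adjusted over the list alone (median -1.27, at the bound 0). The test ran against the median for the factors and for genes of the 2-cell stage. Without the first unpulsed 0 h array 0 pluripotency genes were higher and 1 lower, 1 epithelial gene higher and 2 lower, 1 germline gene, 1 trophoblast gene and 6 erythroid genes lower, and 1 B cell gene higher. Under quantile scaling 3 germline genes and 1 trophoblast gene were lower. Of genes of the 2-cell stage 0 were called without that array, and 2 were higher and 1 lower under quantile scaling (median 0.37). In both alternatives 0 factors and 0 chromatin regulators were called, and the quantile medians of the factors and trophoblast genes were 0.08 and 0.13. Quantile scaling ended the calls of the pluripotency (adjusted p = 0.603), mesenchymal (0.312), germline (0.323), chromatin (0.99), cell cycle (0.99), glycolysis (0.723), MYC (0.46) and housekeeping lists (0.922). The medians of the last 4 turned to -0.04, -0.07, -0.05 and -0.03. Of the called germline genes 1 was below background in both groups.

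The Y-linked genes Eif2s3y (6.08 ± 0.34, adjusted p = 3.16e-12) and Ddx3y (5.17 ± 0.32, adjusted p = 1.89e-11) were among the largest rises. A feature for the X-inactivation transcript was lower, XIST (at least 713-fold, adjusted p = 1.32e-17). The main Xist feature, named after its values were seen, stood between -1.02 and 0.59 in unpulsed cells up to 48 h and at -6.97, -5.22 and -6.95 at 96, 144 and 192 h, where no array was above background. In pulsed cells it stood at -2.08 at 0 h and between -0.95 and 0.27 afterwards. Stromal genes also moved with time in the unpulsed arm. Their median against 0 h was 1.36, 0.66, 1.79, 1.48, 2.35, 1.13, 1.42 and 0.45 from 3 to 192 h. At 48 h, when it was highest, the B cell list stood at -2.21 (0.34 at 96 h), T and NK genes at 1.89 and Xist at -1.02.

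**Figure D1:**
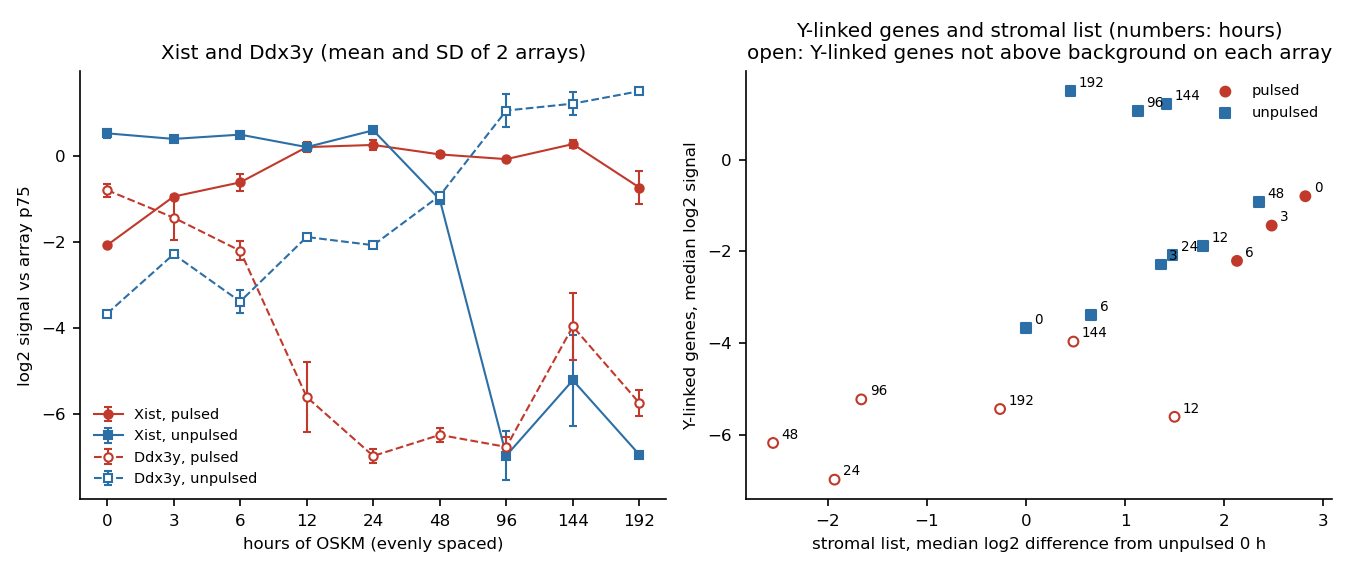
Left, levels of Xist and of the Y-linked gene Ddx3y (log2 against the 75th percentile of each array, mean and SD of 2 arrays) over hours of OSKM in both arms; Xist stood at -6.95 in unpulsed cells, below background, and at -0.74 in pulsed cells at 192 h. Right, the median level of the Y-linked genes against the median log2 difference of the stromal list from unpulsed 0 h, 1 point for each arm and time point (open where the Y-linked genes were not above background on each array), with a stromal median of 2.82 in pulsed cells at 0 h and -2.55 at 48 h.

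Against unpulsed 0 h, 1489 features were called at 3 h (1002 higher, 487 lower), 463 at 6 h (298 and 165), 2933 at 12 h (1596 and 1337), 2682 at 24 h (1565 and 1117), 8682 at 48 h (3249 and 5433), 1463 at 96 h (815 and 648), 4239 at 144 h (1747 and 2492) and 6973 at 192 h (396 and 6577). With quantile scaling the splits from 3 to 48 h were 1593 and 287, 441 and 112, 2420 and 683, 2271 and 785, and 4699 and 3422. At 192 h the split was 2258 and 2783. Without the first unpulsed 0 h array the counts were 3355 at 96 h, 14886 at 144 h and 1451 at 192 h. Without the second they were 13523, 6404, 15027, 10880 and 18596 at 3, 6, 12, 24 and 48 h and 15243 at 192 h. Without the first and the second 192 h array the count at 192 h was 2812 and 2517. Around a curve of time limma called 0 features from 3 to 48 h, with 2354, 2276, 2097, 1939 and 2445 at an unadjusted p under 0.05. It called 6, 27 and 18 at 96, 144 and 192 h.

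Reprogramming after the pulse was followed by comparing pulsed cells at each time point with unpulsed 0 h. By 192 h pluripotency genes were higher in 31 of 34 cases, or 32 adjusted over the list alone, and lower in 1 (median 5.18, relative 3.95). The embryonic gene Dppa5a (at least 4110-fold), Tdh (9.75 ± 0.57), Utf1 (9.14 ± 0.29), Pou5f1 (7.14 ± 0.49, adjusted p = 1.38e-11), Sox2 (at least 34.1-fold), Lin28a (6.61 ± 0.31) and Esrrb (5.15 ± 0.17) were among them. The methylation cofactor Dnmt3l (11.17 ± 0.45) and the demethylase Tet1 (4.87 ± 0.22) were also higher. Epithelial genes were higher in 23 of 23 (median 5.80, relative 4.58), with the keratins Krt18 (8.45 ± 0.50) and Krt19 (7.94 ± 0.55) and the adhesion genes Cdh1 (6.69 ± 0.36) and Epcam (4.66 ± 0.58). The calls of both lists were lost, at adjusted p = 0.0649 and 0.11 with an estimated correlation. B cell genes fell in 25 and rose in 2 of 29 (median -5.69, relative -6.92), with Cd19 (at least 647-fold, adjusted p = 5.32e-16), Spib (-9.08 ± 0.53), the surrogate light chain Igll1 (-8.95 ± 0.13), Pou2af1 (-8.90 ± 0.44) and Ebf1 (-6.02 ± 0.23). This held with an estimated correlation.

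In the pulsed arm Pou5f1, probed on chromosome 17 at 35647280 to 35647340, stood at -5.26 ± 1.06 (SD) at 0 h, 0.90 ± 0.01 at 48 h, 2.16 ± 0.01 at 96 h and 4.13 ± 0.06 at 192 h. Cdh1, probed on chromosome 8 at 109193812 to 109193871, stood at -2.87 ± 0.41 at 12 h, 0.58 ± 0.05 at 24 h, 2.27 ± 0.37 at 48 h and 4.64 ± 0.40 at 192 h. Sox2 stood at -3.72 ± 0.29 at 144 h and 0.27 ± 1.02 at 192 h, and Dppa5a at 2.89 ± 0.19 and 7.19 ± 0.25. At 96 h neither was above background. The epithelial list had a median of 1.90 at 48 h and 2.84 at 96 h, when the pluripotency list stood at -0.20 and -0.09, and the latter reached 3.55 at 144 h. Cd19 stood at 2.50 ± 0.01 at 0 h, 4.46 ± 0.33 at 12 h and 2.55 ± 0.10 at 48 h, so it was no lower at 48 h than at 0 h. It then stood at -0.89 ± 0.12 at 96 h and -4.13 ± 0.25 at 192 h. Cebpa went from 1.72 ± 0.09 at 0 h to -3.28 ± 0.24 at 24 h, while the stromal list went from 2.82 to -1.93. The chromatin gene Tet2, a demethylase, stood at 1.38 ± 0.03 at 0 h, 4.11 ± 0.05 at 24 h and 1.20 ± 1.12 at 192 h, and its probes disagreed.

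**Figure D2:**
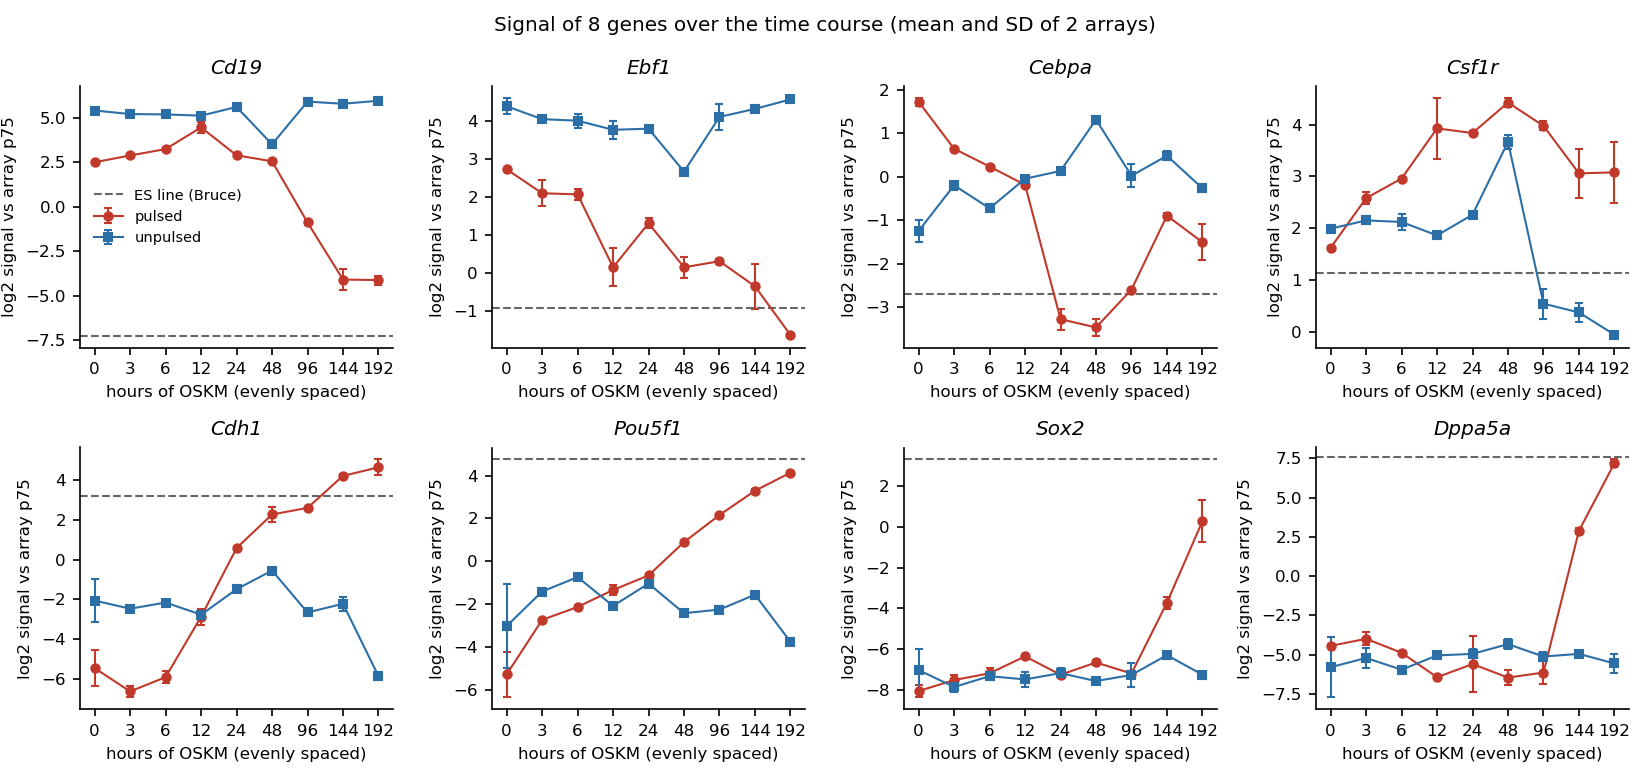
Levels of 8 panel genes (log2 against the 75th percentile of each array, mean and SD of 2 arrays) over hours of OSKM in pulsed and unpulsed cells, with a dashed line at the level in the ES line Bruce. In pulsed cells Cdh1 reached 2.27 and Pou5f1 0.90 at 48 h and Cd19 stood at -4.13 at 192 h, while unpulsed cells had Cd19 at 5.96 at 192 h.

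Interferon genes fell in 25 of 28 by 192 h (median -3.79, relative -5.02), with Ifit3 (-6.21 ± 0.26) and Rtp4 (-6.09 ± 0.21). Inflammatory genes fell in 14 and rose in 3 of 21 (median -1.77), with the acute phase gene Saa3 (7.96 ± 0.36) higher and the chemokine Ccl5 (-3.65 ± 0.21) lower. Myeloid genes fell in 19 and rose in 3 of 32 (median -1.31, relative -2.53), with Mpo (-9.41 ± 0.56) and S100a9 (-8.63 ± 0.15) lower and Csf1r (1.09 ± 0.24) and Itgam (2.64 ± 0.58) higher. Mesenchymal genes fell in 13 and rose in 1 of 18 (median -1.59, relative -2.82), with the growth factors Tgfb3 (-4.16 ± 0.17) and Tgfb1 (-3.68 ± 0.19) and the repressor Zeb2 (-3.91 ± 0.21). Another probe of Zeb2 did not differ, at -1.94 against -1.89, and of 2 other probes of Csf1r 1 gave -0.61. These 4 lists held with an estimated correlation. Stromal genes, at 2.82 in pulsed cells at 0 h, had a median of -1.93 at 24 h and -2.55 at 48 h. At 192 h 3 were higher and 7 lower of 24 (median -0.26, relative -1.49; adjusted p = 0.146 with an estimated correlation). Of the 4 factors 2 were higher and 1, Klf4 (-3.54 ± 0.44), lower (median 3.92, at the bound 2.89), and the list did not pass.

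Other calls at the preset correlation were lost. Trophoblast genes were higher in 14 and lower in 2 of 19 (median 3.24), with the transcription factors Tfap2c (7.05 ± 0.70) and Elf5 (5.40 ± 0.95), and had adjusted p = 0.308 with an estimated correlation. Genes of the 2-cell stage were higher in 8 of 10, or 10 adjusted over the list alone (median 2.02, at the bound 1.49), and in 2 under quantile scaling. They had adjusted p = 0.361 with an estimated correlation. Glycolysis genes were higher in 6 and lower in 2 of 17, with the lactate exporter Slc16a3 (4.61 ± 0.16) and the aldolase Aldoc (3.59 ± 0.13). Their test ran upward at a relative median of -0.56 and had adjusted p = 0.308 with an estimated correlation. Cell cycle genes were higher in 2 and lower in 14 of 30 (adjusted p = 0.28 with an estimated correlation). Cdk1 (-6.21 ± 1.04) was among the lower, whereas its other probes gave 0.75 to 1.95. Immediate early genes were higher in 4 and lower in 7 of 19, with Hspb1 (9.45 ± 0.40) higher and Fos (-4.35 ± 0.40) lower (adjusted p = 0.11 with an estimated correlation). Housekeeping genes were higher in 2 and lower in 4 of 14, with B2m (-6.70 ± 0.48) lower (adjusted p = 0.308 with an estimated correlation).

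Not passing were p53 targets (2 higher and 7 lower of 22), chromatin regulators (8 and 9 of 31) and MYC targets (5 and 6 of 24). Nor did T and NK genes (7 and 6 of 18), erythroid genes (8 and 2 of 17) or germline genes (11 and 0 of 18, with 6 and 3 under quantile scaling). Median and mean differed in sign for chromatin regulators (-0.01 and 0.22), MYC targets (0.22 and -0.05) and T and NK genes (0.38 and -0.54), and the test ran against the median for T and NK genes. Quantile scaling ended the calls of the cell cycle, immediate early, 2-cell-stage and stromal lists (adjusted p = 0.0712, 0.159, 0.308 and 0.106). It turned the median of chromatin regulators to 0.22 and of T and NK genes to -0.20, and left 5 erythroid genes higher and 2 lower. Of the called members 1 epithelial gene, 1 germline gene and 1 gene of the 2-cell stage were below background in both groups.

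The counts against unpulsed 0 h were 13584 at 3 h (2536 higher, 11048 lower), 11135 at 6 h (2140 and 8995), 13538 at 12 h (6106 and 7432), 13384 at 24 h (2877 and 10507), 8446 at 48 h (4302 and 4144), 6126 at 96 h (2667 and 3459), 6100 at 144 h (3094 and 3006) and 19454 at 192 h (14039 and 5415, with a median of 1.23 over all features). Quantile scaling split them into 5248 and 5483 at 3 h, 4872 and 4919 at 6 h, 5832 and 6267 at 24 h and 8073 and 7314 at 192 h. Without the first unpulsed 0 h array the counts were 6773, 4914, 7020 and 9280 at 3, 6, 24 and 144 h, and without the second 17193, 10656 and 10711 at 6, 96 and 192 h. They were 7352 without the second pulsed 6 h array and 12216 without the second pulsed 192 h array, and 834, 569, 407, 1656, 2055, 2467 and 3737 around a curve of time at 3, 6, 12, 48, 96, 144 and 192 h. Slides 2 and 4 each held an array of pulsed 192 h and of unpulsed 0 h. Within them the medians were -5.56 and -5.82 for B cell genes, 4.70 and 5.93 for pluripotency genes and 5.32 and 6.41 for epithelial genes, and 0.58 and -0.90 for p53 targets. The 2 slides also disagreed for germline genes (0.79 and 3.45), genes of the 2-cell stage (1.05 and 3.20), trophoblast genes (1.67 on slide 2 and more on slide 4), erythroid genes (0.44 and 2.18), T and NK genes (-0.61 and 1.09), immediate early genes (-0.24 and -1.28) and chromatin regulators (0.25 and -0.70).

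How the arms differed under OSKM was asked by comparing them at each time point. From 96 h on Xist was lower in unpulsed cells, so a change of donor there may be part of the differences. At 192 h pluripotency genes were higher in pulsed cells in 32 and lower in 1 of 34 cases (median 6.80, at the bound 6.24), with Dppa5a (at least 4610-fold), Tdh (11.28 ± 0.57), Zfp42 (at least 379-fold), Pou5f1 (7.87 ± 0.49, adjusted p = 2e-12) and Sox2 (at least 38.2-fold). Dnmt3l (at least 5120-fold) was also higher. Epithelial genes were higher in 23 of 23 (median 6.71, relative 4.91), with Cdh1 (at least 787-fold), Krt18 (10.27 ± 0.50) and Epcam (6.56 ± 0.58). The adjusted p with an estimated correlation was 0.134 and 0.154 for these lists. B cell genes were lower in 25 and higher in 1 of 29 (median -6.45, relative -8.25), with Cd19 (at least 947-fold), Spib (-9.83 ± 0.53), Vpreb3 (-8.61 ± 0.12) and Rag1 (-6.45 ± 0.34). Interferon genes were lower in 17 of 28 (median -1.34, relative -3.14), with Gbp3 (-4.83 ± 0.24). Mesenchymal genes were higher in 3 and lower in 12 of 18 (median -1.80, relative -3.59), with Tgfb3 (-4.73 ± 0.17) and the filament gene Vim (-3.04 ± 0.20). Stromal genes were higher in 4 and lower in 9 of 24 (median -0.72, relative -2.52), with Fbn1 (-3.89 ± 0.46) and Cxcl12 (-3.77 ± 0.27). The last 4 lists held with an estimated correlation.

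Myeloid genes were higher in 22 and lower in 5 of 32 (median 2.18, relative 0.38), and in 14 and 8 under quantile scaling, and did not pass. Csf1r (3.14 ± 0.24), Itgam (2.68 ± 0.58) and Lyz2 (2.66 ± 0.21) were higher, as was the granule gene Ngp (at least 26.2-fold). Lists that lost their call were cell cycle genes (2 higher and 15 lower of 30) and p53 targets (1 and 10 of 22), each with adjusted p = 0.154 with an estimated correlation. Of the p53 and senescence list, Sesn1 (-3.53 ± 0.27) and Cdkn2a (-2.02 ± 0.12) were lower. Germline genes were higher in 14 of 18 (median 4.37, at the bound 2.37), and 10 were higher and 5 lower under quantile scaling (adjusted p = 0.47 with an estimated correlation). Trophoblast genes were higher in 15 and lower in 2 of 19 (adjusted p = 0.427 with an estimated correlation), and erythroid genes higher in 16 of 17 (median 3.02, at the bound 2.71; adjusted p = 0.351 with an estimated correlation). Housekeeping genes were higher in 1 and lower in 6 of 14 (adjusted p = 0.167 with an estimated correlation).

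Not passing were the factors (2 and 1 of 4), inflammatory genes (6 and 7 of 21), immediate early genes (6 and 4 of 19) and chromatin regulators (8 and 10 of 31). Nor did glycolysis (6 and 2 of 17) and MYC targets (5 and 6 of 24). Genes of the 2-cell stage were higher in 9 of 10 (median 2.84, at the bound 1.55), and 4 were higher and 2 lower under quantile scaling, where their median was -0.22. T and NK genes were higher in 12 and lower in 3 of 18 (median 1.64, at the bound 1.33), and in 8 and 6 under quantile scaling. Median and mean differed in sign for inflammatory genes (-0.10 and 0.26) and chromatin regulators (-0.35 and 0.15), and the test ran against the median for immediate early genes. Under quantile scaling 3 inflammatory genes were higher and 10 lower (median -1.07), and that list and the glycolysis list passed (adjusted p = 0.0413 for each). The cell cycle and germline lists lost their calls (adjusted p = 0.0711 and 0.253). In the same scaling 8 MYC targets were higher and 4 lower (median 0.35), 1 stromal gene higher and 10 lower, 1 mesenchymal gene higher and 14 lower, 11 erythroid genes higher and 1 lower, and 2 housekeeping genes higher and 4 lower. The median of chromatin regulators turned to 0.10. Of the called members 2 germline genes and 1 gene each of the epithelial, mesenchymal, 2-cell-stage, T and NK and erythroid lists were below background in both groups.

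**Figure D3:**
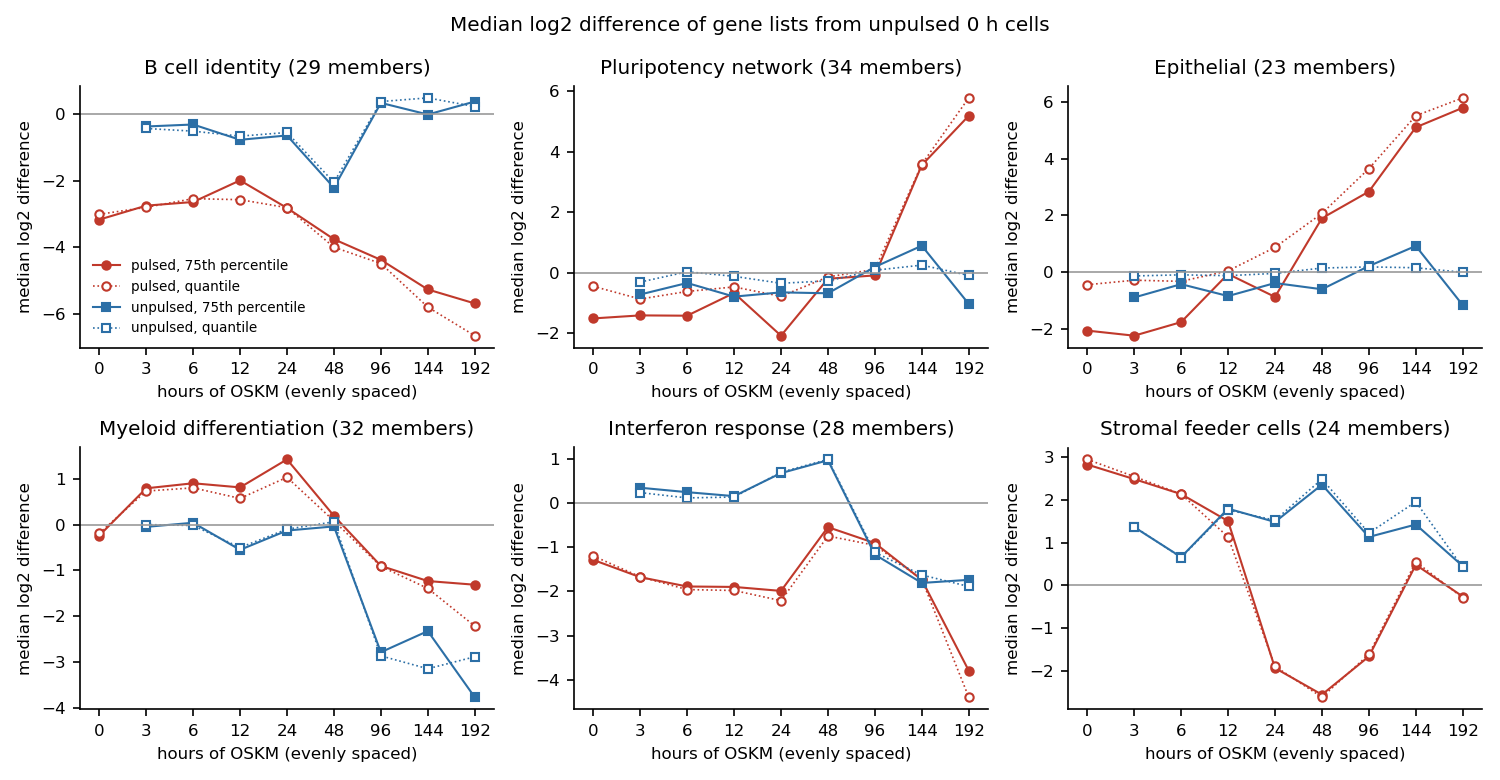
Median log2 difference of 6 gene lists from unpulsed 0 h cells over hours of OSKM in both arms, with solid lines for scaling to the 75th percentile and dotted lines for quantile scaling. At 192 h the B cell list stood at -5.69 in pulsed and 0.38 in unpulsed cells, and the pulsed pluripotency and epithelial lists at 5.18 and 5.80.

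Between the arms 4608 features were called at 3 h (1166 higher and 3442 lower in pulsed cells), 7042 at 6 h (1645 and 5397), 11999 at 12 h (7361 and 4638), 10669 at 24 h (3327 and 7342), 11804 at 48 h (7950 and 3854), 6186 at 96 h (2649 and 3537), 7794 at 144 h (3997 and 3797) and 25646 at 192 h (19746 and 5900, with a median of 1.80 over all features). With quantile scaling the splits from 3 to 48 h were 1648 and 2268, 2839 and 3323, 6141 and 6237, 4501 and 5565, and 4831 and 4730. At 192 h the split was 10942 and 8962. The change from 0 to 192 h differed between the arms for 26312 features, with a higher change in pulsed cells for 20412 and a lower one for 5900 (10892 and 9689 under quantile scaling). Pulsed 192 h differed from pulsed 0 h for 25921, with 20376 higher and 5545 lower (10977 and 8775 under quantile scaling). At 3 h the count was 2917 without the first pulsed and 2874 without the second unpulsed array, and at 6 h 4255 and 4290 without the second pulsed and the second unpulsed array. At 12 h it was 7473 without the second pulsed array and at 24 h 7098 without the second unpulsed array. Around a curve of time the counts were 2472, 1199, 686, 3678, 3303 and 9498 at 3, 6, 12, 48, 96 and 192 h.

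The difference between the arms over the whole course was tested with the time points as 8 pairs, from 0 to 192 h without 24 h. The spread between time points, not between replicate arrays, set its error. B cell genes were lower in pulsed cells in 14 of 29 cases, or 24 adjusted over the list alone (median -3.57), with Spib (-5.95 ± 0.81), Ms4a1 (-5.61 ± 0.77), Rag1 (-5.28 ± 0.66, adjusted p = 0.00726), Ly6d (-4.95 ± 0.65), Ebf1 (-3.29 ± 0.52) and Pax5 (-2.75 ± 0.50). The adjusted p with an estimated correlation was 0.245. Atp1a3 (5.86 ± 0.44, adjusted p = 0.00208), the receptor kinase Mst1r (4.85 ± 0.50), Tgm1 (4.04 ± 0.67) and the stem cell receptor Lgr6 (3.94 ± 0.56) were higher. Of the myeloid list 2 of 32 were higher, the signalling adaptor Tyrobp (3.37 ± 0.64) and the oxidase Cybb (3.04 ± 0.37), or 11 adjusted over the list alone (median 0.66). It had adjusted p = 0.589 with an estimated correlation. Interferon genes were lower in 5 of 28, or 14 adjusted over the list alone (median -1.29), with Ifi44 (-2.61 ± 0.29) and Oasl1 (-2.46 ± 0.45). They too had adjusted p = 0.589 with an estimated correlation.

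Of the pluripotency genes 0 were higher and 1 of 34 lower, the phosphatase Alpl (-3.21 ± 0.34), or 2 and 1 adjusted over the list alone (median 0.94; adjusted p = 0.713 with an estimated correlation). Epithelial genes were called in 0 of 23 (median 1.70; adjusted p = 0.615 with an estimated correlation). Mesenchymal, cell cycle, immediate early and T and NK genes passed only at the preset correlation, each with adjusted p = 0.589 with an estimated correlation. Of mesenchymal genes 1 of 18 was higher, the integrin Itgb3 (2.08 ± 0.28), and 1 higher and 1 lower adjusted over the list alone. No cell cycle gene was called (0 of 30, median -0.34). Of immediate early genes 2 of 19 were higher, with Hmox1 (2.20 ± 0.38), or 6 adjusted over the list alone. Of T and NK genes 2 of 18 were lower, Klrd1 (at least 3.38-fold) and the adaptor Lat (-2.79 ± 0.35). Pou5f1 (2.03, adjusted p = 0.463), Cd19 (-4.45, adjusted p = 0.125) and Cdkn2a (-1.41, adjusted p = 0.0897) were not called.

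The stromal list had 0 of 24 called (median -0.54) and did not pass. Of inflammatory genes Il1b (3.50 ± 0.61) was higher and Cd83 (-2.87 ± 0.34) lower (1 and 2 adjusted over the list alone). The trophoblast gene Ascl2 (4.02 ± 0.59) and the erythroid gene Nfe2 (2.52 ± 0.37) were higher. Adjusted over the list alone, 1 p53 target was higher and 2 lower, 1 chromatin regulator lower, 1 glycolysis gene higher and 1 lower, 1 gene of the 2-cell stage higher, and 1 erythroid gene higher and 1 lower. In these lists, and for MYC targets, germline genes, factors and housekeeping genes, 0 others were called over all genes, and none passed.

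Over all features 426 were called by limma, 131 higher and 295 lower in pulsed cells (median 0.04), of 4798 with an unadjusted p under 0.05. With quantile scaling 1015 were called (458 and 557), the immediate early list lost its call (adjusted p = 0.119), 4 myeloid genes were higher, and 2 pluripotency genes were higher and 1 lower. Without 0, 3, 6, 12, 96, 144 and 192 h the count was 181, 170, 157, 230, 176, 146 and 856. Over 0 to 48 h it was 246, though Xist already differed at 0 h (-2.08 pulsed, 0.52 unpulsed).

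How far the cells stood from pluripotent lines was asked with the ES lines R1 and Bruce (3 arrays), compared first with unpulsed 0 h cells. Pluripotency genes were higher in 30 of 34 cases (median 6.86), with Dppa5a (at least 6360-fold), Fbxo15 (at least 1470-fold), Sox2 (at least 259-fold), Zfp42 (8.40 ± 0.75), Pou5f1 (7.65 ± 0.45), Esrrb (7.29 ± 0.16) and Klf4 (3.39 ± 0.41). Genes of the 2-cell stage were higher in 8 of 10 (median 4.08, at the bound 3.45), with Zscan4e (10.78 ± 0.89) and Zscan4f (at least 583-fold). Immediate early and heat shock genes were higher in 10 and lower in 1 of 19, with Hspb1 (11.69 ± 0.37). B cell genes were lower in 25 of 29 (median -7.43, at the bound -7.05), with Cd19 (at least 1340-fold), Pou2af1 (-11.91 ± 0.42) and Igll1 (-10.72 ± 0.12). Interferon genes were lower in 28 of 28 (median -3.70), with Ifih1 (-6.12 ± 0.12) and Mx1 (-6.05 ± 0.13), and myeloid genes in 25 of 32, or 26 adjusted over the list alone, with S100a9 (-10.32 ± 0.14). Inflammatory genes were higher in 5 and lower in 11 of 21. These 7 lists held with an estimated correlation.

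Epithelial genes were higher in 19 of 23 in ES lines, with Krt8 (7.31 ± 0.67) and Cdh1 (5.02 ± 0.34) (adjusted p = 0.0992 with an estimated correlation). The factors were higher in 3 and lower in 1 of 4, with Myc (-2.88 ± 0.14) lower (adjusted p = 0.109 with an estimated correlation). Cell cycle genes were lower in 7 of 30 (adjusted p = 0.237 with an estimated correlation). Targets of p53 were higher in 11 and lower in 2 of 22 (adjusted p = 0.23 with an estimated correlation). Germline genes were higher in 11 and lower in 1 of 18, with Tex19.1 (at least 908-fold), and had adjusted p = 0.215 with an estimated correlation. Trophoblast genes were higher in 11 of 19 (adjusted p = 0.168 with an estimated correlation). T and NK genes were higher in 3 and lower in 10 of 18, or 11 adjusted over the list alone (adjusted p = 0.285 with an estimated correlation). Not passing were mesenchymal (3 higher and 7 lower of 18), chromatin (8 and 6 of 31), glycolysis (4 and 1 of 17), MYC targets (1 and 0 of 24), stromal (7 and 4 of 24), erythroid (1 and 4 of 17) and housekeeping genes (0 and 2 of 14). Median and mean differed in sign for chromatin (-0.24 and 0.43) and glycolysis genes (-0.03 and 0.25), whose tests ran upward. Without the first unpulsed 0 h array 3 inflammatory genes were higher and 11 lower, and 3 erythroid genes higher and 3 lower. Nanog had 2 probes on chromosome 6, at 122663676 to 122663735 and at 122664590 to 122664649. The brighter, which stood for the gene, was not called (-0.65, adjusted p = 0.221), while the other differed by 10.30.

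In all 9011 features differed between ES lines and unpulsed 0 h (4633 higher and 4378 lower, median -0.11). Pulsed 192 h cells differed from ES lines for 19917 features (15297 higher and 4620 lower; 8629 and 7457 under quantile scaling), or 12392 without the second pulsed 192 h array. Unpulsed 192 h cells differed for 13636 (4374 and 9262; 5927 and 5543 under quantile scaling). Levels at pulsed 192 h and in ES R1 and ES Bruce were 4.13, 4.54 and 4.75 for Pou5f1, 7.19, 8.02 and 7.61 for Dppa5a, 0.27, 3.09 and 3.30 for Sox2, and 4.64, 2.71 and 3.21 for Cdh1. The Pearson r with ES lines across genes ranged from 0.853 to 0.911 over arms and times, at 144 h was 0.911 in pulsed and 0.853 in unpulsed cells, the largest difference, and at 192 h was 0.861 and 0.882. Over 8 time points the mean difference between the arms was 0.00616 (SD 0.026), higher in pulsed cells at 5 of 8, with an exact two-sided sign-flip permutation p of 0.578. ES R1 and ES Bruce correlated with each other at 0.873, so these r values do not rank the arms by nearness to ES cells. At 192 h the arrays also differed in spots above background, with 87.0% and 84.5% in pulsed and 54.6% and 54.9% in unpulsed cells.

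Whether iPS lines differed from ES lines was asked with 3 iPS and 2 ES lines, 1 mean per line. The pluripotency genes Sox2 (0.02 ± 0.28), Pou5f1 (-0.20 ± 0.27), Dppa5a (-0.22 ± 0.32) and Zfp42 (0.78 ± 1.28) were not called, and no panel gene had an adjusted p under 0.928. With limma 0 features were called, with 369 at an unadjusted p under 0.05, and with quantile scaling 0 and 483. No list had a member called, and adjusted over the list alone 1 stromal gene was lower. At the preset correlation the interferon list was higher in iPS lines (median 0.38, relative 0.67; adjusted p = 0.565 with an estimated correlation), as were trophoblast genes (0.41; adjusted p = 0.355 with an estimated correlation). Stromal and mesenchymal genes were higher too (0.44 and 0.32; adjusted p = 0.626 with an estimated correlation for each). So were inflammatory genes (0.10; adjusted p = 0.565 with an estimated correlation), glycolysis genes (0.16; adjusted p = 0.695 with an estimated correlation), p53 targets (0.09; adjusted p = 0.495 with an estimated correlation) and MYC targets (0.10; adjusted p = 0.626 with an estimated correlation). Under quantile scaling the p53 and MYC lists lost their calls (adjusted p = 0.524 for each), and the pluripotency list passed as lower (median -0.25, adjusted p = 0.0295). As reported, no other list passed, B cell, myeloid, pluripotency, chromatin, germline and 2-cell-stage genes among them.

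The value table gives other scanner files to the labels ES R1, ES Bruce, aiPS 8 and aiPS 22, and the results follow the labels of the scanner files. By the table's labels the 2 arrays of ES Bruce would be those of aiPS 8 and ES R1, in which the Y-linked gene Ddx3y stood at -7.01 and 0.45 and Eif2s3y at -7.13 and 1.82. By the labels of the scanner files the 2 arrays of ES Bruce had Ddx3y at -0.69 ± 0.04 (SD). The lines also split between slide 6 and the other slides. Lines on slide 6 correlated with each other at 0.987 to 0.994 across genes. Of the lines on other slides, aiPS 8 correlated with ES R1 at 0.972, although these lay on different slides. Both correlated with the lines on slide 6 at 0.864 to 0.936. Within slide 6, with the spread of technical replicates and not of lines, aiPS 22 and iPS 26 differed from ES Bruce for 709 features. The fit on lines recovered no simulated change, so its count of 0 does not show that the lines were alike.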

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

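The tests on the first principal component, of weaker arrays at 96 to 192 h (in place of the scaled housekeeping median of 0.175, which scaling holds near 0), of Y-linked genes against stromal genes, and of the splits with quantile scaling, were chosen after the result was seen.

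The change from 0 to 192 h differed between the pulsed and unpulsed arms, tested as an interaction, for 26312 features (20581 with quantile scaling), the panel genes that follow among them. The change was higher in pulsed than in unpulsed cells (a positive interaction) for the pluripotency genes Pou5f1 (10.12, adjusted p = 2.19e-11), Sox2 (8.55), Nanog (2.09, or 7.55 for its other probe), Zfp42 (12.33), Esrrb (7.57), Lin28a (7.44), Dppa5a (11.38), Tet1 (6.58) and Dnmt3l (12.46). It was also higher for the epithelial genes Cdh1 (13.89) and Epcam (9.30) and the myeloid genes Itgam (1.84, adjusted p = 0.0413), Lyz2 (2.78) and Csf1r (3.51, or -0.43 for 1 of its other probes). It was lower in pulsed cells (a negative interaction) for the B cell genes Cd19 (-7.18), Ebf1 (-4.53) and Rag1 (-1.73, adjusted p = 0.00244), the mesenchymal and stromal genes Zeb2 (-4.13), Snai2 (-4.86) and Col1a1 (-5.16), and for Cebpa (-4.21), Klf4 (-3.65) and Cdkn2a (-1.25). The other probe of Zeb2 gave 1.49 and that of Rag1 2.03, with the opposite sign. From 0 to 192 h Rag1 went from -5.30 to -5.02 in pulsed and from -0.58 to 1.43 in unpulsed cells. Cdkn2a went up in both arms, from 0.12 to 1.88 and from 0.89 to 3.89, and Lyz2 down in both, from 0.38 to -0.75 and from 0.50 to -3.41. All 23 kept their sign with quantile scaling, with Rag1 at -4.28 and Cdkn2a at -0.55. Several of these genes were below background in some groups, so the sizes are not bounds. The pulsed and unpulsed arms already differed at 0 h, so part of each value is the difference at the start. In unpulsed cells Xist also went from 0.52 at 0 h to -6.95 at 192 h and Eif2s3y from -3.20 to 2.88. A change of donor may therefore be part of each value.

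Xist was lower in unpulsed cells at 96, 144 and 192 h, above background on 0 of 6 arrays, than at 0 to 48 h, by at least 30.7-fold. The Y-linked genes Ddx3y (3.63) and Eif2s3y (4.35) were higher at the same time points, and the median with Uty, whose levels overlapped and which was above background on 1 of the 12 earlier arrays, was 3.63. A loss of Xist transcription alone forbids that median, and weaker arrays are argued against by Ddx3y and Eif2s3y in the signal before scaling, where their median difference was 3.46 and a weaker array would lower every gene. Cells of another sex of donor animal at 96 to 192 h, or an outgrowth of male cells from a mixed sample, may be the source, and the labels give no sex. In the same groups the myeloid list stood at -2.78, -2.32 and -3.76 against 0 h, so a change of donor and the effect of time stay open together for the unpulsed values from 96 h on.

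Stromal genes were higher in pulsed than in unpulsed cells at 0 h in 95.8% of 24 members, with a median of 2.82 and an interquartile range of 0.894, and in 100% with quantile scaling. The background of the first unpulsed 0 h array would need the median without that array to be under 0.5 of this. It was 2.81, although the bound set for the contrary, at least as large as with the array, was missed by 0.01, and a tolerance was set only after the value was seen. A carry-over of stromal cells stays open, for the mesenchymal list (1.25 at pulsed 0 h) and the p53 list (1.20) too: Sparc stood at 8.18 against 6.13 and Col1a2 at 8.03 against 5.67, 21 of the members were above background on both unpulsed 0 h arrays, 0 are in another list, and the labels name a sort that removes feeder cells. Whether male stromal cells were carried over among female B cells could not be told, since the Y-linked genes were above background on both arrays at 3 of 9 pulsed time points, and an induction of these genes by the pulse was not tested.

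The first principal component of all arrays held 43.7% of the variance. Its Pearson r with the percent of spots above background was 0.839 over 44 arrays, and 0.866 over the means of 23 groups (permutation p = 2e-05, Spearman rho 0.86 with permutation p = 1e-05, the smallest that 1e+05 permutations give), which as time points of a culture need not be independent, with 0.801 without the 2 farthest groups. The conditions alone are argued against by the unpulsed 0 h arrays, which lay 53.3% of its range apart, while the next largest gap within a group was 29.1%. Between groups lay 88.8% of its variance, so differences between arrays in background stay open as a part of the component and do not exclude a part due to the conditions.

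For the pulse difference over the time course, 2 of 100 splits that swap the arms within time points gave at least 426 called features, the real split included. This share is under the bound set for chance before the data were examined. Since another split called more features than the real one, the count does not exclude chance. The highest of the others, 7459, swaps the arms at 12, 48 and 192 h and depends on the scaling, and its cause was not tested. With quantile scaling that split called 0 features, the real split 1015 and the highest of the others 2.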

How the results depend on the processing

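Chosen after seeing the data were the fit on bright features only, the value table matched to scanner files, the paired fit up to 48 h and quantile scaling without the first unpulsed 0 h array. The limits of these results lie in the signal over background, the number of arrays and the scaling. Of the alternative values, 368 counts of calls stayed within 1.5 times the reported count and 130 did not, and 4025 counts within gene lists stayed and 679 did not. With an estimated correlation 90 list tests stayed on their side of the threshold and 57 lost the call. Of the values for named genes 9037 stayed on their side of the threshold, 720 lost the call, 48 gained it and 46 with a call changed sign. The spread around a curve of time ended the calls of more named genes than any other alternative, 229, against 62 with normexp background, 62 and 61 with the value table as labelled and as matched, 24 with quantile scaling, 48 with quantile scaling without the first unpulsed 0 h array and 39 without that array alone. Where few spots were above background, down to 51.0% on an array, changes of weak genes are limited by that signal. Unless stated otherwise the cause of a difference was not tested.

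Normexp background, the value table as labelled and the value table as matched gave, in this order, 6157, 6052 and 6142 features for the pulse at 0 h. For unpulsed cells against 0 h they gave 5707, 5616 and 5710 at 48 h and 2026, 1825 and 2024 at 192 h. For pulsed cells against unpulsed 0 h they gave 5838, 5751 and 5791 at 3 h, 4930, 4842 and 4905 at 6 h, 6295, 6237 and 6291 at 24 h, and 11801, 11756 and 11798 at 192 h. Between the arms they gave 2007, 1961 and 1999 at 3 h, 2735, 2653 and 2733 at 6 h, 7566, 7555 and 7583 at 12 h, 5080, 4991 and 5079 at 24 h, 6904, 6821 and 6876 at 48 h, and 14424, 14352 and 14372 at 192 h. For the interaction they gave 16703, 16522 and 16593, and for pulsed 192 h against pulsed 0 h 14475, 14384 and 14406. Against ES lines they gave 11115, 11714 and 11107 for pulsed 192 h and 7808, 7563 and 7813 for unpulsed 192 h. The cause was not tested.

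A spread taken around a curve of time in each arm holds departures of a group from the curve as error, by its construction. It gave 133 features for the pulse at 0 h. For unpulsed cells limma called 0 at 3, 6, 12, 24 and 48 h (2354, 2276, 2097, 1939 and 2445 at an unadjusted p under 0.05), and 6, 27 and 18 at 96, 144 and 192 h. For pulsed cells against unpulsed 0 h it gave 834, 569, 407, 1656, 2055, 2467 and 3737 at 3, 6, 12, 48, 96, 144 and 192 h. Between the arms it gave 2472, 1199, 686, 3678, 3303 and 9498 at 3, 6, 12, 48, 96 and 192 h, and 14628 for the interaction.

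Quantile scaling without the first unpulsed 0 h array gave 6250 features for the pulse at 0 h. For unpulsed cells it gave 909, 300, 1938, 6686 and 1351 at 3, 6, 12, 144 and 192 h, and for pulsed cells against unpulsed 0 h 5824, 4654 and 6562 at 3, 6 and 24 h. Slide as a fixed block gave 3607 at unpulsed 3 h. Within slide 6 the iPS and ES lines differed for 709 features, where the spread of technical replicates and not of lines set the error. On the other slides the count was 619, from 1 array of aiPS 8 against 1 array of ES R1 with the spread taken from other groups, which does not show that these lines differ.

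The pulse difference over the time course was 426 features as reported. It was 1015 with quantile scaling and 823, 818 and 821 with normexp background, the value table as labelled and as matched. It was 728 with 24 h included, 181 with 0 h left out and 246 over 0, 3, 6, 12 and 48 h. With replicate number as a block, which keeps the arrays of a group apart, it was 3706. Replicate numbers did not pair arrays: of 210 pairs of groups the differences between replicates 1 and 2 correlated across genes above 0.1 in 53 and under -0.1 in 35, with a median r of 0.014.

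Leaving out 1 array leaves its group with 1 array, which is assumed to vary like the other groups. The counts then ranged from 6629 to 19516 for the pulse at 0 h. For unpulsed cells they ranged from 1022 to 13523, 321 to 6404, 1986 to 15027, 2007 to 10880, 6506 to 18596, 1202 to 3355, 3515 to 14886 and 1451 to 15243 from 3 to 192 h. For pulsed cells against unpulsed 0 h they ranged from 6773 to 18651, 4914 to 17193 and 7020 to 18851 at 3, 6 and 24 h, and from 5264 to 10656, 6112 to 9280 and 10711 to 25030 at 96, 144 and 192 h. Between the arms they ranged from 2874 to 3387, 4255 to 4908, 7473 to 13705 and 7098 to 10859 at 3, 6, 12 and 24 h, and for pulsed 192 h against ES lines from 12392 to 19500. The largest departures for the time points against 0 h came without the first or the second unpulsed 0 h array, as given beside the counts. For the time course the range was 146 (without 144 h) to 856 (without 192 h).

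Some named genes changed sign (cause not tested). With quantile scaling these were Sox2 (below background, sign unreadable), Dnmt3l (1.40) and Slc16a1 (0.02) for the pulse at 0 h. At unpulsed 192 h they were Tet1 (0.31), Dnmt3l (0.48), Tcstv3 (0.18) and Fap (0.23). They were Zscan4f (-0.04) and Postn (-0.19) for pulsed 192 h against unpulsed 0 h, and Ccl3 (-1.07), Tcstv3 (-0.22), Zscan4c (-0.83) and Dcn (-0.51) between the arms at 192 h. Without the first unpulsed 0 h array as well, Dnmt3l (0.13, unpulsed 192 h) and Zscan4f (-0.14, pulsed 192 h) changed sign. With normexp they were Sox2 and Slc16a1 (0.02) for the pulse, and Tet1 (0.08) and Dnmt3l (0.07) at unpulsed 192 h. Postn (-0.06) did so for pulsed 192 h, and Ccl3 (-0.28), Tcstv3 (-0.05), Zscan4c (-0.02) and Dcn (-0.14) between the arms. Both value table forms gave Sox2, Slc16a1 (0.04) and Zscan4f (0.00) for the pulse, and Tet1 (0.10) and Dnmt3l (0.08) at unpulsed 192 h. Postn (-0.07) did so for pulsed 192 h, and Ccl3 (-0.30), Tcstv3 (-0.08), Zscan4c (-0.05) and Dcn (-0.17) between the arms. With the mean over the probes of a gene Nanog was higher in ES lines than in unpulsed 0 h cells, by 4.82, because its other probe was. Postn at pulsed 192 h ranged from -0.01 to 3.91 with 1 array left out, the former without the second unpulsed 0 h array.

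Similarity to ES lines differed between the arms by -0.00109 to 0.0134 over the alternatives, with an exact permutation p of 0.195 to 0.945.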

Other observations

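The relation of Y-linked to stromal genes was tested after the result was seen.

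The myeloid gene Csf1r, the receptor of a macrophage growth factor, was highest within the course in both arms. In pulsed cells it stood at 1.62 ± 0.03 (SD, n = 2) at 0 h, 4.43 ± 0.09 at 48 h and 3.08 ± 0.59 at 192 h, and the myeloid list had its highest median against unpulsed 0 h at 24 h, 1.42, a group that shared no slide with the rest of the course. In unpulsed cells Csf1r stood at 3.67 ± 0.13 at 48 h and -0.06 ± 0.02 at 192 h, and the interferon list went from 0.96 at 48 h to -1.17 at 96 h. Col1a1 stood at 6.07 ± 0.20 in pulsed cells at 0 h and 0.10 ± 0.08 at 48 h, and at 3.23 ± 0.29 and 5.09 ± 0.06 in unpulsed cells. The mesenchymal repressor Snai2 stood at 3.56 ± 0.05 in pulsed cells at 0 h and -2.67 ± 0.24 at 48 h.

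In the pluripotent lines Xist, chosen after its values were seen, stood between -7.46 and -5.43, above background on 1 array. Ddx3y stood at 0.45 in ES R1 (n = 1) and -0.69 ± 0.04 in ES Bruce, and at -7.01 in aiPS 8 (n = 1), -8.00 ± 0.24 in iPS 26 and -7.76 ± 0.11 in aiPS 22, all below background.

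Male stromal cells carried over in varying amounts may link the Y-linked and stromal genes over time, a hypothesis tested as 2 relations. In pulsed cells the Y-linked genes Ddx3y and Eif2s3y were above background on both arrays at 3 of 9 time points, so the relation there is void, and male carry-over could not be told. Over 6 unpulsed time points from 0 to 48 h the Y-linked median was the level of Ddx3y, which was above background on each array, as was Eif2s3y, while Uty was above it on 1 of 12. There the Pearson r was 0.983 (exact permutation p = 0.00139, adjusted p = 0.00278) and Spearman rho 1 (exact permutation p = 0.00278, adjusted p = 0.00451), with r at 0.987 without the 2 farthest. Unpulsed 96 to 192 h were left out because Xist was lower there, and time points of a culture need not be independent. At pulsed 12 h Ddx3y was below background on both arrays, although the stromal median there was above that of unpulsed 3 h, 1.36, where Ddx3y was above background.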
